A study of Homo sapiens with 4 samples.

How the data were processed

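Gene expression was measured in SK-N-SH cells, a human neuroblastoma line, on the Affymetrix Human Transcriptome Array, with 2 arrays after 24 h of the dioxin TCDD at 1e-10 M and 2 arrays after the solvent, dimethyl sulfoxide (DMSO). The sample titles call the arrays of a group biological replicates, and no label gives a culture, preparation day or hybridisation batch. Groups were taken from the titles. The number of arrays, 2 per group, limits the precision of every value given here.

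The deposited values were log2 signals that the authors had made with RMA, per the submitters' processing notes. RMA as generally described corrects background, normalizes probes by quantiles and summarises the probes of a feature, but the settings, version and summary level were not given in the sources used here. Interquartile ranges of the arrays ran from 2.00 to 2.21 log2 units over the features analysed here, which need not share 1 distribution even after quantile normalization of all probes. Such differences in contrast between arrays can move bright and dim features in opposite directions, so other scalings were tried.

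The table analysed here held 13493 features whose identifiers start with chromosomes 1 to 5, and features of the remaining chromosomes were not analysed here. CYP1A1, CYP1A2, NQO1, ALDH3A1, AHR and ACHE were therefore not analysed here. Gene names came from the platform annotation and were updated through RefSeq names for GRCh38.p14, which was used for names and neighbouring genes only. Of the features, 6647 had 1 gene symbol, 341 had several and 6505 had no symbol here. Symbols of 5930 features were matched by Entrez identifier, 618 as current symbols and 97 through 1 synonym, while 2 were kept as given. Features with several symbols were tested but not named, except those that AHRR and UGT1A genes share. Values of 314 features were identical to those of another feature.

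Each feature was tested with limma 3.58.1 in R 4.3.3, with lmFit and eBayes on the log2 values, 2 arrays against 2 without a block, 2 residual degrees of freedom and 4.27 prior degrees of freedom. P-values are two-sided and were adjusted over all features by the Benjamini-Hochberg method, and a feature was called at an adjusted p under 0.05. A second count used an unadjusted p under 0.05 and a change of at least 1.5-fold. A change is the TCDD mean minus the DMSO mean on the log2 scale, with the moderated standard error (SE). Confidence intervals are at 95%.

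Before the data were examined, 36 gene lists were fixed, covering targets and partners of the aryl hydrocarbon receptor (AhR), neuroblastoma cell states, neuronal genes, stress and signalling pathways, metabolism, structural RNAs, reference genes and markers of other cell types. For lists, a gene was represented by its feature with the highest mean over the 4 arrays, giving 6574 genes. The 29 lists with at least 5 measured genes were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. Medians of lists were also set against 10000 random lists matched on signal in 20 bins. Families of genes with similar names, such as olfactory receptors, were added after the values had been seen.

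The genes named were fixed by rule before the data were examined. They are the 12 largest called rises and the 12 largest called falls among features with 1 symbol and non-overlapping groups, a set of AhR genes with ACHE, and up to 3 genes per list with the smallest p. The other features of a gene are mentioned where they differ in direction or in whether they were called. The 12 largest called rises and falls of protein-coding genes, and further members of families and lists, were named after the values had been seen.

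The functions were tested on simulated arrays of 13493 features with the spread of the real ones, but with noise drawn independently for each feature. The simulated arrays held no difference in contrast and no correlation between genes. Their error shares and list p-value therefore need not hold for the real arrays. With 200 features changed, 164 were called, of which 19 were false (11.6%), and the share recovered was 12% at a change of 0.25, 82% at 0.5, 96% at 0.75 and 100% at 1 on the log2 scale. With 4000 features changed by 0.3, 3493 were called and 108 of these were false (3.09%). In the simulated list test on 6574 genes, a shift of 0.2 in 11 genes gave an adjusted p of 4.4e-13, with 0 of the other lists called.

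Alternatives fixed before the data were examined were a replicate block, quantile normalization, median centring, removal of the dimmest 25% or 50% of features, a trended robust prior, array weights, averaging of a gene's features (features with exactly 1 symbol), each array left out in turn, other fold thresholds, and other list tests. Cyclic loess normalization, identical features counted once, protein-coding features alone, in the fit or only in the adjustment, and limma's treat at 1.2-fold were added after the data had been seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.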

Results

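RNA of SK-N-SH cells, an adherent human neuroblastoma line, was profiled on 4 arrays to ask which transcripts differed after 24 h of a low concentration of TCDD, 1e-10 M. TCDD is a persistent environmental pollutant and a ligand of AhR, a transcription factor that induces xenobiotic-metabolising enzymes. There were 2 TCDD arrays and 2 DMSO arrays. Median signals lay between 8.19 and 8.22 on the log2 scale. Across features, the arrays of a group correlated at 0.997 (DMSO) and 0.999 (TCDD), and arrays of different groups at 0.989 to 0.994. Features are not independent replicates. The SD of the difference between arrays was 0.132 for the DMSO pair, 0.0855 for the TCDD pair and 0.187 to 0.254 across groups. No pair of arrays shared more than 2 identical values of 13493.

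Genes known as AhR targets differed little between TCDD and DMSO in this table. TIPARP, an AhR-induced ADP-ribosyltransferase that represses the receptor, read 8.63 ± 0.069 in DMSO and 8.66 ± 0.051 in TCDD (log2, SD, n = 2 arrays each), a difference of 0.028 (SE 0.060, limma adjusted p = 0.745) with a 95% interval from -0.12 to 0.17. CYP1B1, a cytochrome P450 enzyme of the classical AhR response, was represented by 2 features that disagreed. The brighter read 8.42 ± 0.063 in DMSO and 8.41 ± 0.0065 in TCDD (difference -0.012, SE 0.055, limma adjusted p = 0.888). The dimmer rose from 7.71 ± 0.031 to 7.95 ± 0.027, by 0.24 (SE 0.052, limma adjusted p = 0.033), and was not called without DMSO replicate 2 (0.21), TCDD replicate 1 (0.26) or TCDD replicate 2 (0.22). The change of the dimmer CYP1B1 feature was 0.27 under quantile normalization (limma adjusted p = 0.045) and 0.27 after cyclic loess (limma adjusted p = 0.034). Without DMSO replicate 1 it was 0.26. ARNT, the dimerisation partner of AhR, differed by 0.15 (SE 0.053, limma adjusted p = 0.089), which did not pass, and by 0.030 after cyclic loess and 0.017 under quantile normalization.

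Of 25 listed AhR targets, 10 were measured by a feature with 1 symbol, and 1 of them rose over all features tested. It was LMCD1, a LIM-domain cofactor (0.20, SE 0.052, adjusted p = 0.048), whose change was 0.11 after cyclic loess normalization (adjusted p = 0.108). It was not called without DMSO replicate 2 (0.17), TCDD replicate 1 (0.21) or TCDD replicate 2 (0.19). Adjusted over the list alone, 0 of the 10 passed. AHRR, a listed target, shared its feature with PDCD6, and that feature differed by 0.078 (SE 0.057, limma adjusted p = 0.336). UGT1A1 and UGT1A6 shared a feature with other UGT1A genes, which differed by -0.092 (SE 0.050, limma adjusted p = 0.215). HES1, a Notch effector, differed by 0.16 (SE 0.050, adjusted p = 0.072), and by 0.10 after cyclic loess. The median change of the list was 0.040, at percentile 60.8 of random lists of matched signal, with a camera p of 0.814 and a p of 0.829 with an estimated correlation. Of the 2 measured AhR partners and cofactors, 0 passed over all features and 0 adjusted over the list alone.

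**Figure D1:**
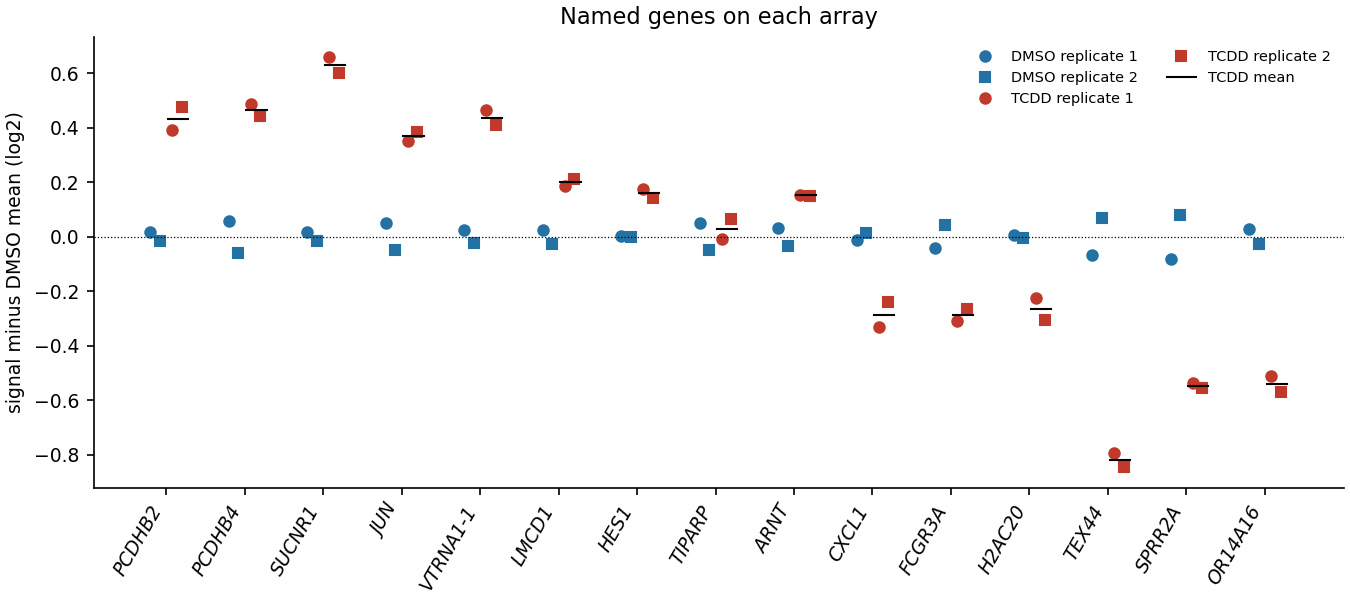
Signal of 15 named genes on each array, as the log2 difference from the DMSO mean, with circles for replicate 1, squares for replicate 2 and a bar for the TCDD mean. TIPARP lies within the spread of the arrays (0.028), JUN lies above (0.37) and TEX44 below (-0.82).

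Over all features, 2351 of 13493 were called by limma (17.4%), 1270 higher and 1081 lower in TCDD. The changes were small, with a median size of 0.32 on the log2 scale, or 1.25-fold, and 221 called features changed at least 1.5-fold (122 higher, 99 lower). At an unadjusted p under 0.05 with at least 1.5-fold, 226 features passed (124 higher, 102 lower), against 357 (149 higher, 208 lower) without DMSO replicate 1. The groups did not overlap for 71.7% of features, against 33.3% expected by chance for a given split of the arrays. Features on the same arrays move together and only 3 splits exist, so this share does not by itself separate treatment from chance. The count of 2351 fell to 644 without DMSO replicate 2 (370 higher, 274 lower) and to 1138 without TCDD replicate 1 (546 higher, 592 lower), was 1626 without TCDD replicate 2 (805 higher, 821 lower), and rose to 4661 without DMSO replicate 1 (2571 higher, 2090 lower).

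Features with no symbol here held 1425 of the 2351 calls and 172 of the 221 calls of at least 1.5-fold, and were not named. At an unadjusted p under 0.05 by limma, 27 features rose at least 2-fold, but no rise named here reached that size. Among named genes, the largest changes lay in short non-coding genes. Of the 24 genes taken by rule, 16 were microRNA genes, 3 were 5S ribosomal RNA pseudogenes and 2 were small nucleolar or Cajal body RNA genes. MicroRNA features also varied more between replicates than protein-coding features. The SD of the difference across features was 0.175 against 0.096 for the DMSO pair, and 0.115 against 0.054 for the TCDD pair. A ranking by size of change can therefore favour microRNA genes without a preferential response. RNA5SP113, a 5S pseudogene, fell by 1.59 (SE 0.11, limma adjusted p = 0.0031), from 10.1 ± 0.18 to 8.55 ± 0.17 (SD, n = 2 each). MIR561 fell by 1.38 (SE 0.070, limma adjusted p = 0.0012) and RNA5SP56 by 1.04 (SE 0.050, limma adjusted p = 0.0012). MIR4434 rose by 0.92 (SE 0.16, limma adjusted p = 0.020) and MIR3684 by 0.83 (SE 0.061, limma adjusted p = 0.0032). MIR9-1, a precursor of the neural microRNA miR-9, rose by 0.79 (SE 0.079). MIR3115, MIR378D1, MIR3140, MIR3682, MIR553 and MIR449A rose by 0.62 to 0.78, and SNORD92 and SCARNA1 by 0.66 and 0.63. MIR488, RNA5SP154, MIR578, MIR4666A, MIR4432, MIR1246 and MIR3131 fell, with changes from -1.09 to -0.75, as did the transcribed pseudogene C3orf86P, by 0.76. Without DMSO replicate 2 the calls of MIR3140 (0.45), SNORD92 (0.46), MIR4434 (0.72), MIR1246 (-0.66) and MIR4666A (-0.67) were lost, and those of MIR3140 (0.80), SNORD92 (0.65) and MIR4434 (0.94) also under quantile normalization, as was that of MIR3140 after cyclic loess (0.80). Whether these features report precursors, mature forms or host transcripts was not determined, and 18 of the 24 lay under a mean signal of 8.38, below which 95% of olfactory receptor genes lay.

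Among protein-coding features, 379 of 5229 rose and 200 fell, and 8 of these changed at least 1.5-fold, 1 higher and 7 lower. At or above a mean signal of 8.38 there were 327 rises and 60 falls, and below it 52 rises and 140 falls. SUCNR1, the receptor for succinate, rose by 0.63 (SE 0.053, limma adjusted p = 0.0044), and TEX44, a testis-expressed gene, fell by 0.82 (SE 0.065, limma adjusted p = 0.0038). Chosen after their values were seen, the next largest rises were TMEM81 (0.58), the beta protocadherins PCDHB4 (0.47) and PCDHB2 (0.43), BBS5 (0.42), a subunit of the ciliary BBSome, and EXOC8 (0.42), a subunit of the exocyst. The next largest falls, chosen in the same way, were KPLCE (-0.73) and LELP1 (-0.72), genes of the epidermal differentiation region, the olfactory receptors OR2T34 (-0.70) and OR13G1 (-0.67), and SPRR2F (-0.65), a small proline-rich gene of the cornified envelope. Of these 12 genes only TEX44, PCDHB4 and LELP1 had a mean signal above 8.38, and the other 9, SUCNR1 and TMEM81 among them, lay under that level, as 95% of olfactory receptor genes did. Without DMSO replicate 2 the calls of TMEM81 (0.55), PCDHB2 (0.42), EXOC8 (0.38), KPLCE (-0.65), LELP1 (-0.49), OR2T34 (-0.74) and OR13G1 (-0.63) were lost, that of LELP1 also under quantile normalization (-0.79) and after cyclic loess (-0.80). After cyclic loess normalization 139 of the 379 rises and 144 of the 200 falls were still called. Protein-coding calls numbered 12 higher and 31 lower without DMSO replicate 2, 40 and 65 without TCDD replicate 1, 50 and 102 without TCDD replicate 2, and 1414 and 456 without DMSO replicate 1. The 379 and 200 calls depended on adjustment together with the other features. With the same p-values adjusted over protein-coding features alone, 2 passed (1 higher, 1 lower), and with the spread also estimated from protein-coding features alone, 1771 did (1300 higher, 471 lower).

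Of 9 measured mesenchymal-type neuroblastoma genes, 3 rose and 0 fell, and 4 rose adjusted over the list alone. They were PRRX1, a mesenchymal homeobox factor (0.26, SE 0.051), the TGF-beta receptor TGFBR2 (0.22, SE 0.049) and NOTCH2 (0.22, SE 0.059), and the list had a camera adjusted p of 0.267. Of 8 noradrenergic neuroblast genes, HAND1 rose by 0.22 (SE 0.057), with 0 adjusted over the list alone (camera adjusted p = 0.702). Of 5 cholinergic genes, 1 rose over all features and adjusted over the list alone, the nicotinic receptor subunit CHRNB2 (0.20, SE 0.054, camera adjusted p = 0.742 for the list). Of 5 genes of the neuronal cytoskeleton and synapse, 7 glutamate and GABA receptor genes and 8 retinoid and steroid receptor genes, 0 passed over all features or adjusted over the list alone (camera adjusted p = 0.898, adjusted p = 0.702 and adjusted p = 0.796). Of 9 ion channel genes, TRPC1 rose by 0.25 (SE 0.066), with 0 adjusted over the list alone (camera adjusted p = 0.791). After cyclic loess normalization PRRX1 (0.17), NOTCH2 (0.098), HAND1 (0.095), CHRNB2 (0.076) and TRPC1 (0.24) were no longer called. No call in this paragraph held without DMSO replicate 2 (changes of 0.17 to 0.27), TCDD replicate 1 (0.22 to 0.28) or TCDD replicate 2 (0.18 to 0.25).

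Adhesion and guidance genes included several rises. Their list medians lay at percentile 98.85 (migration and matrix), 53.3 (axon guidance), 81.5 (TGF-beta) and 89.8 (Wnt and Notch) of random lists of matched signal. Of 7 migration and matrix genes, the integrin subunits ITGA6 (0.26, SE 0.050) and ITGA4 (0.23, SE 0.057) rose, and 5 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.339). The cadherin CDH6 differed by -0.27 (adjusted p = 0.051). Of 19 axon guidance genes, the semaphorin receptors PLXNA2 (0.22, SE 0.051) and PLXNA1 (0.22, SE 0.057) and the ligand SLIT2 (0.25, SE 0.056) rose, and 4 rose adjusted over the list alone (camera adjusted p = 0.661). Of 8 TGF-beta genes, LTBP1 (0.26, SE 0.054) and TGFBR2 rose, also the 2 that rose adjusted over the list alone (camera adjusted p = 0.294). Of 8 Wnt and Notch genes, CTNNB1, which encodes beta-catenin (0.21, SE 0.053), and NOTCH2 rose, and 4 rose adjusted over the list alone (camera adjusted p = 0.607). After cyclic loess normalization PLXNA2 (0.11), PLXNA1 (0.098), SLIT2 (0.16), CTNNB1 (0.089) and NOTCH2 (0.098) were no longer called, nor under quantile normalization was ITGA4 (0.25). No call in this paragraph held without DMSO replicate 2 (changes of 0.17 to 0.28), TCDD replicate 1 (0.19 to 0.29) or TCDD replicate 2 (0.19 to 0.27).

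Immediate early genes included a rise and a fall. JUN, a subunit of AP-1, rose by 0.37 (SE 0.057, limma adjusted p = 0.015) and EGR4, a zinc-finger factor, fell by 0.24 (SE 0.054, limma adjusted p = 0.035), 1 each of 8 measured, with 2 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.702). The median of that list was -0.0015 and its mean 0.019. Of 11 inflammatory genes, the chemokine CXCL1 fell by 0.29 (SE 0.056, limma adjusted p = 0.025), also the 1 that fell adjusted over the list alone (camera adjusted p = 0.702, direction down, while the median was 0.036). Of 5 interferon response genes, IFI6 rose by 0.21 (SE 0.055), also adjusted over the list alone (camera adjusted p = 0.702). Of 11 cell cycle genes, the phosphatase CDC25A rose by 0.30 (SE 0.071), with 0 adjusted over the list alone (camera adjusted p = 0.731). After cyclic loess normalization IFI6 (0.089) and CDC25A (0.20) were no longer called. None of the 5 was called without DMSO replicate 2 (JUN 0.32, EGR4 -0.25, CXCL1 -0.27, IFI6 0.18, CDC25A 0.21), only JUN without TCDD replicate 1 (EGR4 -0.28, CXCL1 -0.24, IFI6 0.24, CDC25A 0.31), and only JUN and CXCL1 without TCDD replicate 2 (EGR4 -0.20, IFI6 0.18, CDC25A 0.30).

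Among metabolic lists, nuclear-encoded oxidative phosphorylation genes had the smallest camera p, 0.0082 (adjusted 0.205), which was 0.395 with an estimated correlation. Of the 9 measured, NDUFB5, a subunit of complex I (0.23, SE 0.050), and COX5B, a subunit of cytochrome c oxidase (0.27, SE 0.061), rose, and 7 rose adjusted over the list alone. Of 6 cholesterol synthesis genes, PMVK (0.21, SE 0.050) and the sterol carrier gene STARD4 (0.22, SE 0.057) rose, and 4 rose adjusted over the list alone (camera adjusted p = 0.267). None of these 4 genes was called after cyclic loess normalization (NDUFB5 0.13, COX5B 0.14, PMVK 0.14, STARD4 0.14), nor without DMSO replicate 2 (changes of 0.18 to 0.23), TCDD replicate 1 (0.18 to 0.29) or TCDD replicate 2 (0.20 to 0.25). Of 8 hypoxia, 8 fatty acid, 3 glycolysis, 6 heat shock, 6 endoplasmic reticulum stress, 8 p53, 7 circadian and 10 cytosolic ribosomal protein genes, 0 passed over all features or adjusted over the list alone. Camera adjusted p-values of these lists lay between 0.262 and 0.878, with the 3 glycolysis genes too few for a test. Of 6 NRF2 genes, 0 passed over all features and 2 rose adjusted over the list alone, with differences of 0.18 for SQSTM1 and 0.22 for SLC7A11 (adjusted p over all features 0.063 and 0.069, camera adjusted p = 0.503 for the list), and SQSTM1 differed by 0.066 after cyclic loess. The reference genes SDHA (0.16, and 0.049 after cyclic loess) and TFRC (0.063) did not pass, and TFRC turned to -0.070 under quantile normalization and -0.063 under cyclic loess.

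Of 8 measured spliceosomal and other small RNA genes, the vault RNA VTRNA1-1 rose by 0.44 (SE 0.054, limma adjusted p = 0.0090) and RNU11, of the minor spliceosome, by 0.35 (SE 0.076, limma adjusted p = 0.031), and 3 rose adjusted over the list alone (camera adjusted p = 0.337). The 2 features of RNU5F-1, a U5 RNA gene of that list, both lay higher in TCDD, but only the dimmer was called. The brighter differed by 0.30 (SE 0.086, limma adjusted p = 0.058), with a 95% interval from 0.095 to 0.51. The dimmer rose by 0.23 (SE 0.053, limma adjusted p = 0.036), with an interval from 0.10 to 0.36. The dimmer was not called without DMSO replicate 2 (0.25), TCDD replicate 1 (0.20) or TCDD replicate 2 (0.26). Of 46 listed small nucleolar RNAs 7 were measured, and 0 passed in either count (camera adjusted p = 0.607). The 1 measured replication-dependent histone gene, H2AC20, fell by 0.27 over all features (SE 0.054, limma adjusted p = 0.027). With 1 gene, adjustment over the list alone leaves p unadjusted and adds no further test. Of 5 immune-cell markers, FCGR3A, an immunoglobulin Fc receptor, fell by 0.29 (SE 0.056, limma adjusted p = 0.025), also adjusted over the list alone. That list had a camera p of 0.014 (adjusted 0.205), which was 0.129 with an estimated correlation. Of 2 Schwann and glial markers, FOXD3 (-0.19) and GFRA3 (-0.14) did not pass over all features and were lower adjusted over the list alone. The 1 endothelial and 1 epithelial marker did not pass. VTRNA1-1 was called without any 1 array, RNU11 was not called after cyclic loess (0.23) or without DMSO replicate 2 (0.26) or TCDD replicate 1 (0.31), and H2AC20 and FCGR3A were not called without DMSO replicate 2 (-0.27 and -0.25), TCDD replicate 1 (-0.31 and -0.27) or TCDD replicate 2 (-0.23 and -0.31).

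**Figure D2:**
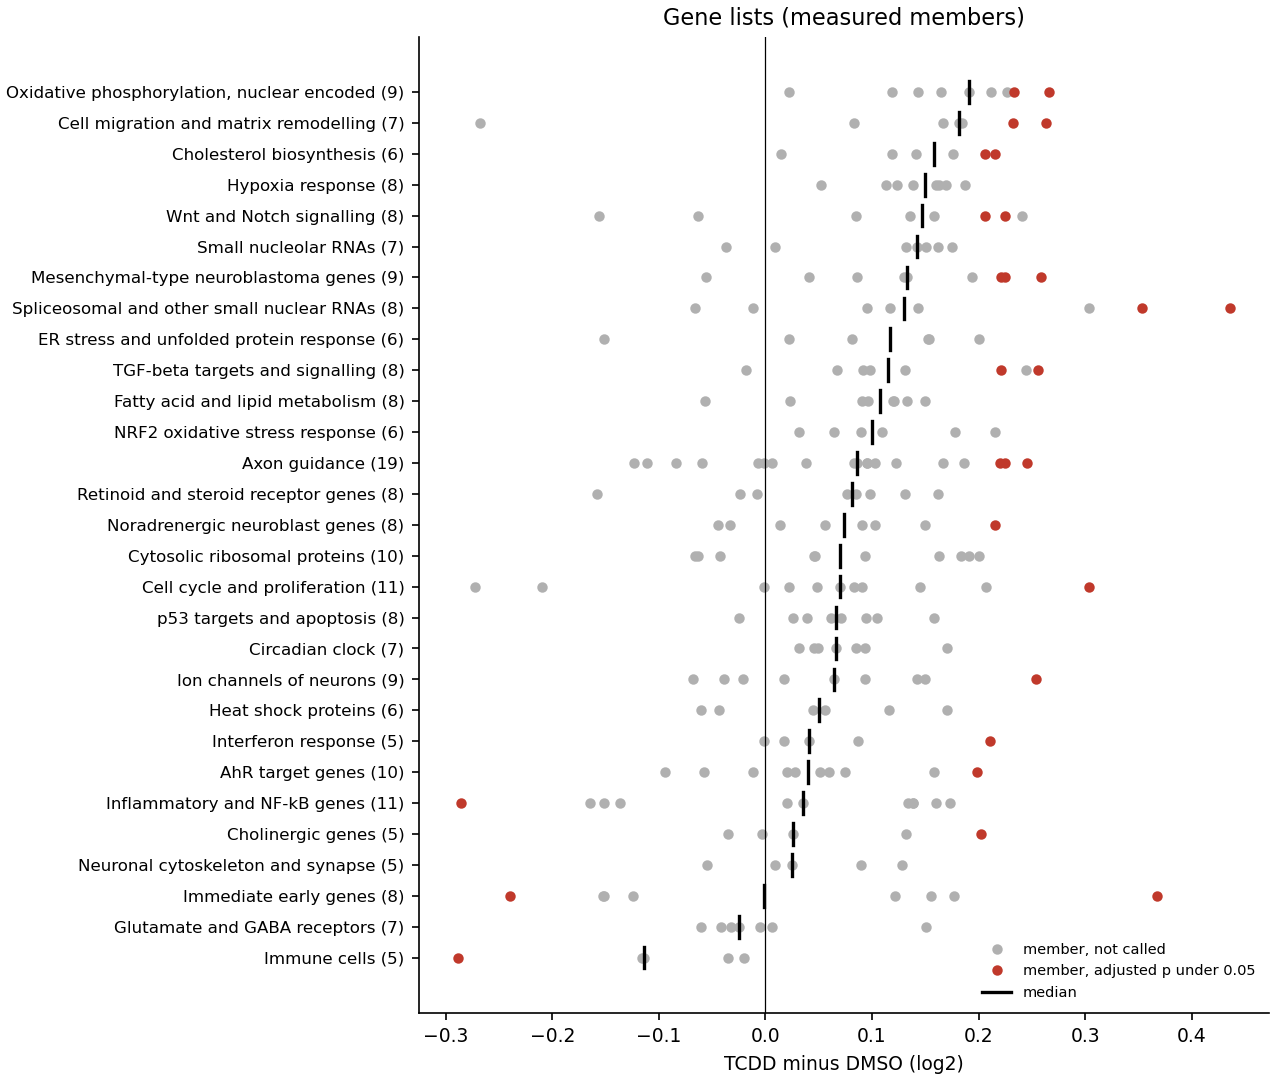
Log2 change, TCDD minus DMSO, of each measured member of the 29 tested lists, with called members in red, a black bar at each median and the number measured in parentheses. Of the medians 26 lie above 0 and 3 below, and 9 of the 29 change sign after cyclic loess normalization, 8 under quantile normalization and 1 under median centring.

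With camera 0 of the 29 lists passed an adjusted p under 0.05, 5 had an unadjusted p under 0.05, and with an estimated correlation 0 passed at either threshold. With fry 1 list passed, the immune-cell markers, lower in TCDD (adjusted p = 0.0086). That call was lost with a replicate block (fry adjusted p = 0.312), under quantile normalization (adjusted p = 0.0905), under median centring (adjusted p = 0.210) and with any 1 array left out (adjusted p from 0.116 to 0.375). Fry's test for change in either direction passed for 14 lists, but for 0 with a replicate block, under median centring, without the dimmest 50% of features or without either TCDD array, for 1 without DMSO replicate 2, and for 23 under quantile normalization, 24 after cyclic loess and 16 without DMSO replicate 1, and fry compares no list with other genes. Across the lists, 235 genes were measured, of which 23 rose and 4 fell. That share lay near the 11.1% called among protein-coding features, and 17.4% of all features were called. An unadjusted limma p under 0.05 was reached by 5332 of 13493 features. Members that pass adjusted over a list alone therefore do not by themselves set that list apart. After cyclic loess normalization 6 of the 23 rises were still called, those of JUN, VTRNA1-1, ITGA6, ITGA4, TGFBR2 and LTBP1, as were the 4 falls of FCGR3A, CXCL1, H2AC20 and EGR4. Of the 27 calls, 27 held without DMSO replicate 1, 1 without DMSO replicate 2, that of VTRNA1-1, 2 without TCDD replicate 1 and 4 without TCDD replicate 2. Of the 27 genes, ITGA6, ITGA4, CXCL1, FCGR3A and VTRNA1-1 had a mean signal under 8.38.

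Change depended on signal. With features in 10 bins of rising signal, in the dimmest 5 bins the median change lay between -0.068 and -0.030, and in the brightest 3 bins between 0.10 and 0.13. The DMSO arrays differed from each other along the same axis, with replicate 2 minus replicate 1 between 0.039 and 0.082 in the dimmest 5 bins and between -0.084 and -0.064 in the brightest 3. The TCDD arrays differed by a median of less than 0.01 in every bin. In the TCDD mean minus the DMSO mean, called features of the brightest bin were 158 higher and 14 lower, and of bin 2 81 higher and 153 lower. No label separates treatment from preparation or hybridisation, so any such batch cannot be told apart from the group.

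**Figure D3:**
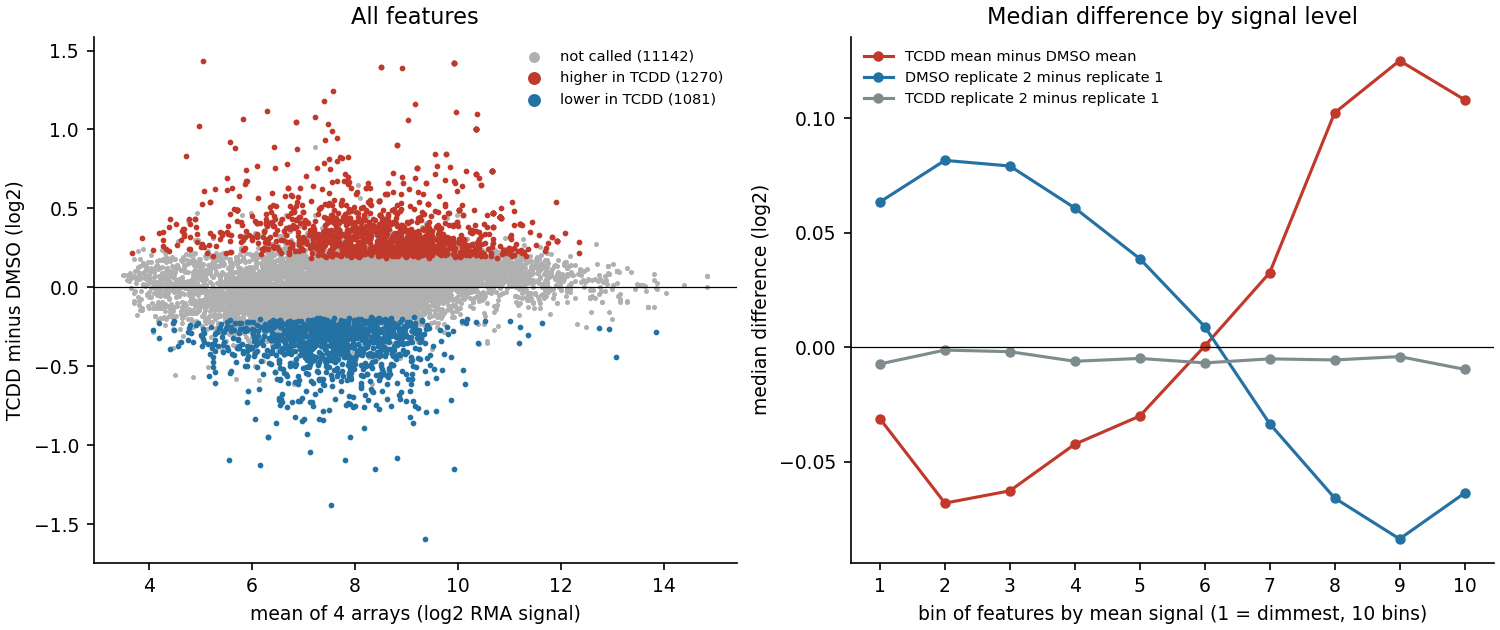
Left, TCDD minus DMSO (log2) against the mean log2 signal of the 4 arrays for 13493 features, with 1270 called higher in red and 1081 called lower in blue. Right, the median difference by bin of signal for the groups and within each pair of replicates, where the groups differ by 0.13 and the DMSO arrays by -0.084 in bin 9.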

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

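Cyclic loess, protein-coding features alone, identical features counted once and treat were chosen after the data were seen, and except where stated the cause of a change was not tested. The number of called features, 2351, became 3634 with a replicate block, 1478 under quantile normalization (1317 of them shared), 1771 over protein-coding features alone (2 when only the adjustment was confined to them) and 70 with treat at 1.2-fold, which tests against a larger change. It ranged from 644 to 4661 when 1 array was left out, with 4661 without DMSO replicate 1, 644 without DMSO replicate 2, 1138 without TCDD replicate 1 and 1626 without TCDD replicate 2, where the lone array was assumed to vary like the other group. Deviations of same-numbered arrays correlated across features at 0.037, but 2 pairs are too few to tell whether same-numbered arrays shared a culture or day. Other settings gave 1713 to 2690 calls, with 1893 after cyclic loess (1576 shared). The 226 features at 1.5-fold became 100 without the dimmest 50% of features, 44 after averaging a gene's features (13 higher, 31 lower), as many as already had 1 symbol among the 226, since features with no symbol or several were left out, and 8 over protein-coding features (1 and 7), and 36 at 2-fold (27 and 9) and 1988 at 1.2-fold (more lower than higher) by construction. Leaving out 1 array gave 203 to 357, the latter without DMSO replicate 1, and identical features counted once gave 99 higher and 101 lower. The count of lists past camera stayed 0 in each setting run, while fry's count, 1, became 0 with a replicate block, under quantile normalization and median centring and with any array left out, was 0 without the dimmest 25% or 50%, where the immune-cell list was not tested, and became 4 with features averaged and after cyclic loess. The AhR list's median, 0.040, stayed above 0 in each setting run, but only just after cyclic loess (0.0011), from 0.019 to 0.047 with 1 array left out, and fry, which tests the list's own genes alone, passed it at an unadjusted p of 0.023. Genes that changed sign had not been called. Under quantile normalization they were NCOA1 (-0.039), BCHE (0.028), MAP2 (-0.042), GABRB1 (0.015), XPC (-0.016), SNORD78 (-0.0023), CLOCK (-0.044), PER3 (-0.026) and TFRC (-0.070). Under cyclic loess they were TIPARP (-0.0044), NCOA1 (-0.030), BCHE (0.033), GATA2 (-0.0037), MAP2 (-0.037), GABRB1 (0.029), XPC (-0.0087), ENO1 (-0.020), CLOCK (-0.030), PER3 (-0.023) and TFRC (-0.063). CYP1B1 was 0.11 with its features averaged. With 1 array left out the ranges were -0.056 to 0.033 for the brighter CYP1B1 feature, -0.021 to 0.077 for TIPARP, -0.090 to 0.020 for BCHE, -0.096 to 0.013 for GABRB1 and -0.0017 to 0.13 for TFRC. Each crossed 0 without DMSO replicate 2 except the CYP1B1 feature, which did so without DMSO replicate 1. TIPARP and BCHE also crossed 0 without TCDD replicate 2. The dimmer CYP1B1 feature, called with all arrays, ranged from 0.21 to 0.26. Signal over background limits the dim features: 58.7% of calls, against 54.2% of all features, lay under the signal below which 95% of olfactory receptor genes lay.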

Other observations

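All tests in this part were chosen after the result was seen, except that of the genes neighbouring the beta protocadherins, whose resampled range was also added afterwards. Small nucleolar and Cajal body RNA genes, which guide modification of ribosomal and spliceosomal RNA, lay higher in TCDD as a family. Of 46 measured, 19 rose and 1 fell, and the median change was 0.22, against 0.020 to 0.11 for random lists of matched signal. It was 0.17 under quantile normalization, 0.18 after cyclic loess and 0.20 against DMSO replicate 1 alone. DMSO replicate 2 minus replicate 1 had a median of -0.055, so replicate 1 lay on the side of TCDD. The small nucleolar RNA list fixed beforehand had 7 measured genes, of which 0 passed, with a median of 0.14 and a camera adjusted p of 0.607. SCARNA1 rose by 0.63, SNORD75 by 0.47, SCARNA18 by 0.45 and SNORA74A by 0.40. The rises numbered 5 without DMSO replicate 2, where SNORA74A was not called (0.35), 9 without TCDD replicate 1, and 11 under quantile normalization. The camera p was 1.7e-06, and 0.089 with an estimated correlation (adjusted p = 0.228 over the families).

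Of 39 measured immunoglobulin kappa V segments 6 fell and 0 rose, where 17.4% of all features were called. The median change of the segments was -0.064, with the largest falls in IGKV3-7 (-0.61) and IGKV3D-20 (-0.55). Their camera p was 5.3e-05, and 0.127 with an estimated correlation. The kappa segments had 3 falls and 1 rise under quantile normalization, and 5 falls and 1 rise after cyclic loess. Of 6 USP17-like genes, near-identical deubiquitinase copies, 5 fell and the median was -0.46, but USP17L12 and USP17L21 held identical values, so they are not separate measurements (camera p = 8.6e-07, and 0.152 with an estimated correlation). Of 163 5S pseudogenes 24 rose and 18 fell, and of 288 microRNA genes 54 rose and 40 fell (camera adjusted p = 0.614 and adjusted p = 0.128 over the families). Of 7 gamma protocadherins 2 rose and of 4 alpha protocadherins 1 rose, with a camera p of 0.136 for the gamma genes and no test of the alpha genes. Under quantile normalization 0 gamma and 0 alpha genes were called, and after cyclic loess 0 gamma and 1 alpha. Without DMSO replicate 2 the kappa segments had 3 falls, the USP17-like genes 0 (median -0.36), the 5S pseudogenes 14 rises and 7 falls, the microRNA genes 22 and 17, and the gamma and alpha protocadherins 0 rises. Without TCDD replicate 1 the kappa segments had 3 falls, the 5S pseudogenes 11 rises and 14 falls, the microRNA genes 26 and 29, and the gamma protocadherins 1 rise. Without TCDD replicate 2 the 5S pseudogenes had 20 rises and 11 falls and the gamma and alpha protocadherins 0 rises, and without DMSO replicate 1 the 5S pseudogenes had 32 rises and 34 falls, the gamma protocadherins 3 rises and the alpha 0.

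The 2351 calls could in part follow a difference in contrast between arrays. After cyclic loess normalization 67.0% were still called (95% interval 65.1% to 68.9%). A contrast that this method removes therefore does not account for all calls. Of the protein-coding calls 48.9% were (44.7% to 53%), with 72.0% of the falls (65.2% to 78.1%) but 36.7% of the rises (31.8% to 41.7%). These intervals count features as independent, which features on the same arrays are not. They measure no variation between arrays or cultures, so the share of calls due to contrast was not decided. Ranges over resampled features or genes, here and below, have the same limit. In the 240 rises that lost their call the median went from 0.23 (SE 0.056) to 0.14 (SE 0.041). Of these, 224 would have passed with the earlier change and the later SE, and 6 with the later change and the earlier SE. With only the limit on p changed, from 0.0087 to 0.0070, 164 would have passed, so the smaller change and the stricter limit both had a part. The total degrees of freedom also fell, from 6.27 to 4.80, and their part was not tested apart. The smaller SD of the difference between DMSO replicate 1 and a TCDD array exceeded that between the DMSO arrays by 0.055. That excess ranged from 0.050 to 0.059 over 1000 resamples of features. For these arrays it argues against a deviation of DMSO replicate 2 alone, but how such SDs vary between arrays was not measured. The covariance of the group difference with the difference of the DMSO arrays lay 0.0023 above the most that noise of 1 array gives. That distance ranged from 0.0017 to 0.0030 over resampled features. It goes with an axis on which the DMSO arrays also differ, with the same limit. After removal of the medians by bin of signal the covariance was 0.0074 against a bound of 0.0071. The 3 splits of the arrays are too few for a share under 0.05, with 2351 calls in the real split, the 1 split that reached that count, and 0 as the highest other, so a response to TCDD and an unrecorded batch stay open and cannot be told apart.

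Olfactory receptor genes, whose products are not known to serve these cells, lay lower in TCDD, with 22 of 71 called lower and 1 higher and a median of -0.19 (-0.15 after cyclic loess and -0.16 under quantile normalization; 4 lower without DMSO replicate 2 and 8 without TCDD replicate 1, where the median was -0.12), and so did cornified envelope genes, with 16 of 45 lower, 0 higher and a median of -0.16 (5 lower without DMSO replicate 2, 9 without TCDD replicate 1, 10 without TCDD replicate 2, 9 under quantile normalization; camera p = 3.8e-16 and 8.1e-12, but 0.124 and 0.137 with an estimated correlation). Random lists of matched signal had medians from -0.088 to -0.017, so other genes of such signal did not fall as far as the olfactory receptors. The family was picked for its low values, and its genes had an estimated correlation of 0.23, which random lists ignore. These ranges therefore do not exclude a shift that depends on signal. Against DMSO replicate 1 alone the median was -0.14, outside -0.054 to 0.0086 for matched lists. The fall was thus also seen without DMSO replicate 2, with the same limits on the range. The axis on which the DMSO arrays also differ stays open, since DMSO replicate 2 lay above replicate 1 by a median of 0.078 (0.035 to 0.10 over resampled genes), within 0.036 to 0.086 for matched lists and not clearly apart from the 0.10 that this axis would give. Background or cross-hybridised signal was not tested and may contribute to these values of -0.19 and -0.16.

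Beta protocadherins, neuronal adhesion molecules encoded in a cluster on chromosome 5, lay higher in TCDD, with 11 of 15 called higher, 0 lower and a median of 0.22, also 0.22 under quantile normalization and after cyclic loess (3 called without DMSO replicate 2, 4 without TCDD replicate 1 and 3 without TCDD replicate 2, with medians of 0.22 to 0.23; camera p = 9.2e-06, and 0.042 with an estimated correlation, adjusted p = 0.228 over the families). Matched lists had medians from -0.072 to 0.11, so other genes of such signal did not rise as far. Against DMSO replicate 1 alone the median was 0.22, outside -0.067 to 0.095 for matched lists, so the rise was also seen without DMSO replicate 2. The family was picked for its values, so these ranges do not exclude a shift that depends on signal or a deviation of DMSO replicate 2. The 20 nearest measured protein-coding genes outside the clusters had a median of 0.14 (0.082 to 0.18 over resampled genes), with 1 called, DELE1 (0.27). That median lay below the lower quartile of the family, 0.182. The quartile rests on 15 genes and its own spread was not measured, so this narrow gap does not decide on a shift of the whole region. These genes are similar in sequence, so shared probe signal, which was not tested, may make the 15 values fewer than 15 separate measurements. A response of the cluster to TCDD, a hypothesis found and tested on the same data, remains open. So do a shift of the whole region and an unrecorded batch.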
